A study of Mus musculus with 2 samples.

How the data were processed

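Single-cell RNA was measured with droplet libraries (10x Genomics Chromium) from dissociated mouse midbrain tissue, labelled as the substantia nigra pars compacta. There were 2 libraries, 1 for control mice and 1 for mice injected with maneb and paraquat (MNPQ), so the groups had no replicates. Per the labels, the MNPQ mice received paraquat at 10 mg/kg and then maneb at 30 mg/kg, 2 times a week for 3 weeks. The labels call the control mice untreated, while the treatment protocol describes saline injections. They also give the sex as pooled, while the protocol describes a random choice of 3 males per group. The tissue came from a punch in a 1 mm slice, was digested with papain at 2 mg/ml for 30 minutes at 34 °C and was triturated for 35 minutes.

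The deposited matrices hold counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, from Cell Ranger 3.0.2 per the file headers and with the mouse genome build mm10 per the labels. The matrices list 31053 genes, and each barcode sums to at least 500 UMIs. How the barcodes were chosen is not stated. Of the gene identifiers, 30934 were found in GENCODE M21, which is on the same assembly and gave the coordinates.

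Cells were kept with at least 200 genes and at most 20% mitochondrially encoded UMIs. This removed 223 of 1105 control barcodes (20.2%) and 111 of 965 MNPQ barcodes (11.5%). Both libraries were clustered together, without batch integration. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was split by the Leiden method at resolution 1.0. Mixed clusters of at least 40 cells were clustered once more with 8 neighbours, which turned 16 clusters into 25. Clusters were named from 23 fixed marker lists, and 6 of them met no list's criteria and stayed unnamed. A class is written with the ending -like, because it rests on marker genes alone. Neuron subtype lists were used for naming clusters as neuron-like only. Doublets called by Scrublet, 7 of 882 control cells and 6 of 854 MNPQ cells, were kept in.

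The share of each class was given per library with its exact (Clopper-Pearson) 95% binomial interval. For gene levels, UMIs were summed over the cells of a class in each library and scaled to the class total (CPM). Each log2 ratio of MNPQ over control has an exact conditional binomial 95% interval. These intervals and the limits for a count of 0 (3 counts) cover counting error only, not variation between cells, mice, dissections or libraries. No test was made and no count of changed genes is given, since cells of 1 library are not replicates. Named genes and lists were compared in the 5 classes with at least 30 cells in both libraries and over all kept cells. For Gm42418, AY036118 and Malat1 ratios are also given in the smaller classes, a choice made after the values were seen.

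The genes named per class had at least 60 UMIs over both libraries and at least 5 in each, with no more than 20% of either library's UMIs in a single cell. The 10 highest and the 10 lowest log2 ratios were taken in astrocyte-like, neuron-like and microglia-like cells, the 3 highest and 3 lowest in the other classes, and the 5 highest and 5 lowest over all kept cells. Some of these genes are left out of the text. A gene under 5 UMIs in 1 library and with at least 60 in the other qualified too, at most 3 per class. Markers of dopaminergic neurons, Xist and the Y-linked genes were always given. Within a gene list, examples were the highest, the lowest and the most abundant member with at least 60 UMIs.

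There were 34 gene lists. A list's median log2 ratio was taken over its genes with at least 20 UMIs in the class, where at least 5 such genes were measured. It was set against 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. The lists, the marker lists, the filters, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were other cell filters, other clustering resolutions, a class per cell from marker scores, clustering without stress, mitochondrial and ribosomal genes, doublets left out, other scalings, each cell weighted equally, cells thinned to 1000 UMIs, other UMI minimums for the lists, markers of other classes left out of the lists, and classes weighted equally. Weighting the classes equally took only the 5 classes with at least 30 cells in both libraries. Thinning to 1000 UMIs left out every cell with fewer UMIs, so it used 440 of 882 control and 409 of 854 MNPQ cells. Weighting the clusters of a class equally, leaving out cells with over 1% hemoglobin UMIs, and taking only cells with at least 1000 UMIs for the shares, were added after the data were seen. A share difference or list median counted as moved when it left the main value by more than 0.5 times the width of the counting interval or of the central 95% of random lists, and a gene ratio when it left its counting interval.

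The calculation of intervals and list percentiles was tested on simulated Poisson counts per gene and library, without single cells. It therefore checks the calculation only, and not the intervals where UMIs of a gene vary between cells. Of 8384 simulated genes, 200 were given a known change, and 95.53% of the intervals held the true ratio. A raised list took percentile 100 and a lowered list percentile 0, while 12 of 200 unchanged lists lay outside the central 95%. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.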

Results

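The data were UMI counts per gene in single cells from the midbrain of mice given maneb and paraquat, a pair of pesticides used to model Parkinson's disease, and of control mice. Each group had 1 library and no replicates, so every difference given here is between 2 libraries. The control library held 1105 barcodes with 2209810 UMIs, and the MNPQ library held 965 barcodes with 2061939 UMIs. The median barcode had 855 UMIs and 477 genes in the control library, and 892 UMIs and 504 genes in the MNPQ library. After filtering, 882 control cells with 2002640 UMIs and 854 MNPQ cells with 1958634 UMIs remained. Their median depth was 974 UMIs in the control and 945.5 in the MNPQ library, and 50.1% and 52.1% of them had fewer than 1000 UMIs. Hemoglobin transcripts made up 2.52% of all control UMIs and 1.33% of all MNPQ UMIs, and 0.392% and 0.453% of those in kept cells.

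The tissue label names the brain region whose dopaminergic neurons degenerate in Parkinson's disease, so the markers of these neurons were counted first. Th (ENSMUSG00000000214), the rate-limiting enzyme of dopamine synthesis on chromosome 7 (142892752 to 142931128, minus strand, mm10), had 1 UMI in the control library. In the MNPQ library it had 0 UMIs in 965 barcodes, which allows a share of barcodes with a UMI of up to 0.311%. The dopamine transporter gene Slc6a3 (ENSMUSG00000021609) also had 1 UMI in the control and 0 in the MNPQ library, with that same limit. Slc18a2, which encodes the vesicular monoamine transporter, had 4 and 1 UMIs. Ddc, the enzyme that turns L-DOPA into dopamine, had 44 and 65 UMIs, but only 2 and 4 of these lay in neuron-like cells, while endothelial-like cells held 18 and 33 and oligodendrocyte-like cells 21 and 19. A Ddc UMI was seen in 1.61% of control and 2.78% of MNPQ neuron-like cells (median depth 787.5 and 788 UMIs), in 1.56% and 2.82% of cells of unnamed clusters (612.5 and 616 UMIs), in 0 of 321 and 4 of 304 astrocyte-like cells and in 0 of 158 and 0 of 118 microglia-like cells, so Ddc in neuron-like cells is not told apart from a background of free RNA. Whether dopaminergic neurons were lost could not be assessed, because Th and Slc6a3 each had only 1 UMI in the control and 0 in the MNPQ library. Clusters were not named by neuron subtype, so the lack of a dopaminergic class adds nothing to these counts. The labels give the slice position without a sign, so the position of the dissected tissue is not certain.

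Both libraries held Y-linked transcripts at close levels. Eif2s3y had 172 UMIs in the control and 179 in the MNPQ library, Ddx3y had 161 and 160, Kdm5d had 35 and 32, and Uty had 29 and 23. Xist, the RNA of the inactive X chromosome, had 2 UMIs in the control library and 0 in the MNPQ library, where up to 0.311% of barcodes with a UMI are allowed by that count.

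The class shares describe the cell make-up of the 2 libraries, in which treatment and dissection cannot be told apart. Astrocyte-like cells were the most common class in both libraries, at 36.4% of control cells (321 cells) and 35.6% of MNPQ cells (304 cells). Microglia-like cells made up 17.9% of the control library (95% interval 15.4 to 20.6) and 13.8% of the MNPQ library (11.6 to 16.3), a difference of -4.1 percentage points (-7.52 to -0.655). Their shares lay closer together without any cell filter, at 14.7% (162 of 1105 barcodes) and 12.4% (120 of 965). They lay further apart, at 16.1% and 10.1%, with at least 500 genes and at most 10% mitochondrial UMIs. No interval was computed under these filters, so whether the unfiltered difference exceeds counting error is not settled. Mature oligodendrocyte-like cells made up 6.12% (4.63 to 7.91) and 9.48% (7.6 to 11.7), a difference of 3.36 percentage points (0.839 to 5.93). Ependymal-like cells, whose kind lines the ventricles, made up 3.17% of control cells (28 cells) and 0.703% of MNPQ cells (6 cells), a difference of -2.47 percentage points (-3.9 to -1.2). Neuron-like cells made up 14.1% (124 cells) and 16.9% (144 cells), and that difference of 2.8 percentage points was within counting error (-0.6 to 6.21). Endothelial-like cells were at 8.28% and 7.96%, pericyte-like cells at 2.83% and 3.28%, smooth muscle-like cells at 1.7% and 2.34%, oligodendrocyte precursor-like cells at 2.04% and 0.937%, and vascular fibroblast-like cells at 0.227% and 0.703%. The intervals of these last differences all held 0. Cells of unnamed clusters were 7.26% and 8.31%, and their leading genes were those of myeloid cells or of myelin. With at least 500 genes and at most 10% mitochondrial UMIs per cell, the differences were 7.36 percentage points for oligodendrocyte-like and -4.89 for ependymal-like cells. Without any cell filter the neuron-like difference turned to -0.814, and with a class per cell from marker scores the vascular fibroblast-like difference turned to -0.307.

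**Figure D1:**
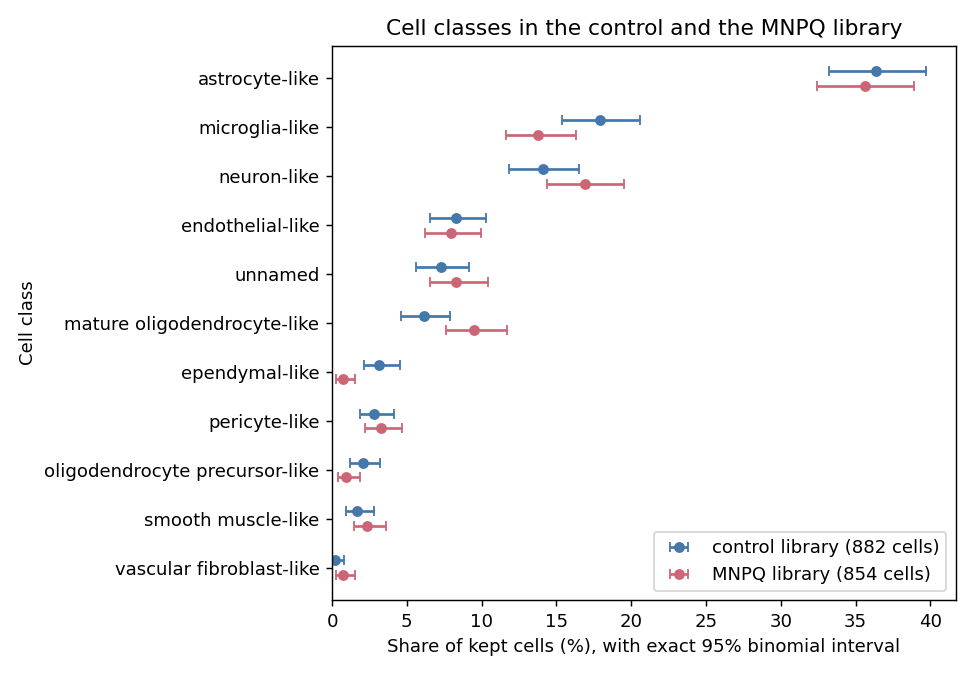
Share of kept cells (%) of each class in the control library (882 cells) and the MNPQ library (854 cells), with exact 95% binomial intervals that cover counting error only. Ependymal-like cells were at 3.17% and 0.703%, and oligodendrocyte-like cells at 6.12% and 9.48%.

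In astrocyte-like cells, antioxidant enzymes, nuclear-encoded subunits of the respiratory complexes and ribosomal proteins were mostly higher in the MNPQ library, while mitochondrially encoded genes and genes for glutamate and ion handling were mostly lower. The medians of antioxidant enzymes and of complexes III to V were smaller with the clusters of the class weighted equally. The comparison rests on 321 control cells with 528837 UMIs and 304 MNPQ cells with 513942 UMIs. Itih3 (ENSMUSG00000006522), a secreted protein of the hyaluronan-binding inter-alpha-trypsin inhibitor family, was at 1750 CPM in the control and 327 CPM in the MNPQ library, 5.34-fold lower (log2 ratio -2.42, 95% interval -2.66 to -2.18). Sparc, a secreted matrix-associated glycoprotein, was 3.47-fold lower (2720 and 784 CPM). Nupr1 (ENSMUSG00000030717), a stress-induced regulator of transcription, was 7.12-fold higher in the MNPQ library (22.7 and 161 CPM, log2 ratio 2.83, 1.95 to 3.84). Id4 (ENSMUSG00000021379), an inhibitor of DNA binding by helix-loop-helix proteins, was 3.94-fold higher (144 and 566 CPM, log2 ratio 1.98, 1.61 to 2.36), and Igfbp2, which binds insulin-like growth factors, was 3.18-fold higher (231 and 734 CPM).

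The other lowest ratios in astrocyte-like cells were those of Gm42418 (-3.01), Hba-a1 (-2.49), Hbb-bs (-2.31), the AMPA receptor subunit Gria1 (-1.96), AY036118 (-1.79), 5031439G07Rik (-1.74), Rbm5 (-1.71) and the Wnt inhibitor Sfrp5 (-1.70). Hba-a1 and Hbb-bs are erythroid markers, and no cluster was named erythroid in either library. The other highest ratios were those of Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (2.00), Cend1 (1.88), the calcium channel gene Orai1 (1.71), Cdc42se1 (1.69), the proteasomal ubiquitin receptor gene Adrm1 (1.65), the carbonyl reductase gene Cbr3 (1.59) and Pmp22 (1.58). By position on mm10, Itih3 lies on chromosome 14 (30908572 to 30923760), Nupr1 on chromosome 7 (126623249 to 126630861) and Id4 on chromosome 13 (48261228 to 48266026), and all of them are annotated as protein-coding.

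The median log2 ratio over astrocyte-like genes with at least 60 UMIs was itself 0.165, so list medians are also given relative to it. Of 14 antioxidant enzymes, 13 were higher in the MNPQ library, with a median of 0.43 (percentile 97.95 of random lists) or 0.26 relative to the class median. Prdx6, a peroxiredoxin and the most abundant of them, was at 887 and 1625 UMIs (log2 ratio 0.915, 0.796 to 1.03), and the lowest was Txn2 (-0.305, -0.778 to 0.163). Of 18 NRF2 target and glutathione genes 12 were higher, with a median of 0.275 that lay inside the range of random lists (percentile 88.05). Of 32 measured nuclear subunits of respiratory complexes III to V, 32 were higher, with a median of 0.43 (percentile 99.99; 0.27 relative), from Cox6c at 0.212 to Cox7b at 1.01. Of 36 nuclear complex I subunits, 34 were higher, with a median of 0.345 (percentile 97.72; 0.18 relative), the highest being Ndufa6 (0.776). The 13 mitochondrially encoded genes went the other way, 11 of them lower, with a median of -0.18 (percentile 0.645), although the median was 0.048 when each cell weighed the same. All 64 cytosolic ribosomal protein genes were higher, with a median of 0.352 (percentile 99.7; 0.19 relative). Among 10 genes for glutamate and ion handling, 7 were lower, with a median of -0.38 (percentile 0.02), and among these the bicarbonate transporter gene Slc4a4 was at 318 and 162 UMIs (-0.93, -1.21 to -0.65). Glul, the glutamine synthetase of that list, was higher (0.35, 0.26 to 0.44). Of 8 immediate early genes 7 were higher, with a median of 0.51 (percentile 97.92), led by Rhob (1.25, 0.60 to 1.93).

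The 2 libraries differed in the kind of astrocyte-like cells they held. A shallow cluster made up 46.7% of control and 75.7% of MNPQ astrocyte-like cells, a deeper cluster 34.0% and 20.7% (median depth 2569 and 4714 UMIs), and a cluster led by Itih3, Agt and Slc6a11 19.3% and 3.62%. Within the deeper cluster, Itih3 was at 742 and 120 UMIs (-2.45), Nupr1 had a log2 ratio of 3.76, Id4 one of 1.99 and Slc4a4 one of -1.11. In the shallow cluster, which held 150 control and 230 MNPQ cells, Itih3 was at 29 and 40 UMIs (-0.139, -0.865 to 0.603). The log2 ratios there were 1.53 for Nupr1, 1.70 for Id4 and 0.21 for Slc4a4 (-0.474 to 0.922). The cluster led by Itih3 had a similar depth (median 662.5 and 628 UMIs, against 680.5 and 678). Clusters were drawn from these same counts, so shallow cells with Itih3 may have been placed in that cluster. Itih3 in the shallow cluster alone therefore cannot show whether its level differed in shallow cells. In the cluster led by Itih3, with 62 control and 11 MNPQ cells, Itih3 was at 152 and 8 UMIs (-1.77, -3.01 to -0.756), Slc4a4 at 30 and 5 (-0.108, -1.83 to 1.27), Id4 at 1 and 3 and Nupr1 at 0 in both libraries, so the interval of Slc4a4 lay below 0 in the deeper cluster only. Slc1a2 and Slc1a3 of the same list were lower in the deeper cluster (-0.785 and -0.544) and also in the shallow one (-0.447, -0.644 to -0.248, and -0.38, -0.67 to -0.0886). In the cluster led by Itih3 the intervals of Slc1a2 and Slc1a3 held 0. With the clusters weighted equally, the median was 0.142 for antioxidant enzymes and 0.275 for complexes III to V. Both lay inside the range of random lists found without this weighting (-0.109 to 0.419 and 0.08 to 0.358). The ratio was then -0.211 for Sfrp5, -0.935 for Gria1 and 0.831 for Pmp22. Thinning to 1000 UMIs kept only 134 control and 105 MNPQ astrocyte-like cells. In these cells the median was 0.715 for complex I and 0.935 for complexes III to V, and the ratio was 1.83 for Nupr1, 2.89 for Igfbp2, 0.352 for Cdc42se1 and -2.72 for Sfrp5.

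**Figure D2:**
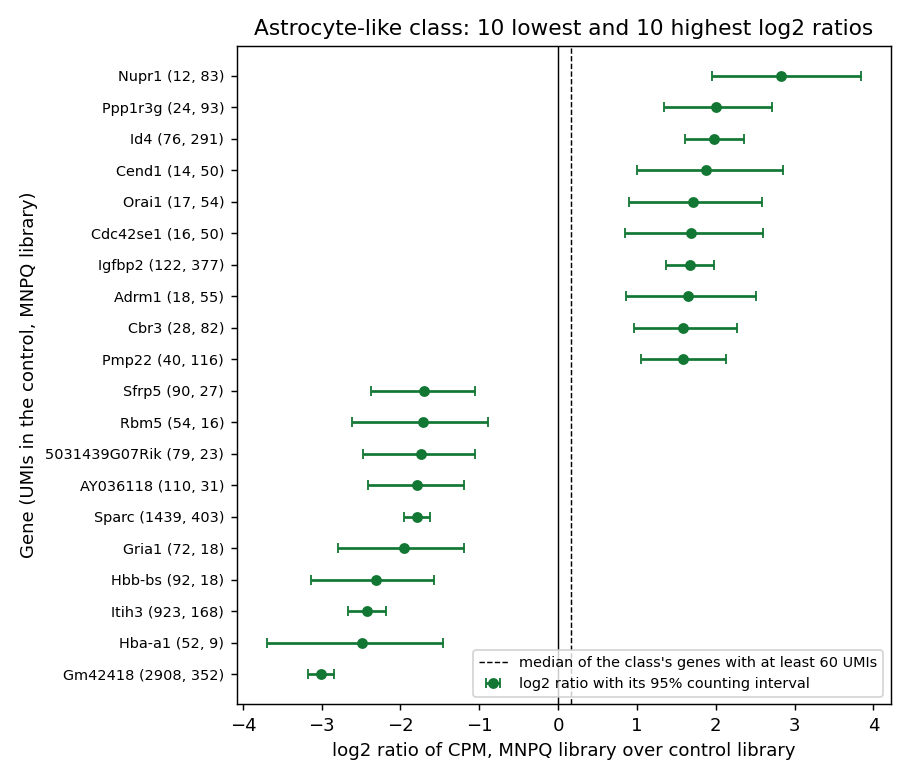
Log2 ratio of CPM, MNPQ over control library, for the 10 lowest and 10 highest named genes of the astrocyte-like class, with 95% counting intervals and, beside each gene, its UMIs in both libraries. The dashed line is the median of the class at 0.165, and the ratios run from -3.01 (Gm42418) to 2.83 (Nupr1).

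In neuron-like cells, genes of the synapse were higher in the MNPQ library and heat shock protein genes lower. The comparison rests on 124 control cells with 184306 UMIs and 144 MNPQ cells with 161265 UMIs. All of the 12 synaptic genes except Dnm1 (-0.265) were higher, with a median of 0.66 (percentile 99.96 of random lists), and the most abundant, Snap25 of the vesicle fusion machinery, was at 186 and 286 UMIs (0.81, 0.54 to 1.09). Slc17a7 (ENSMUSG00000070570), the vesicular glutamate transporter typical of cortical and hippocampal neurons, was 2.09-fold higher (315 and 657 CPM, log2 ratio 1.06, 0.587 to 1.55), and 24 of 124 control and 65 of 144 MNPQ neuron-like cells had a UMI of it, against 1 of 321 and 9 of 304 astrocyte-like cells (median depth 823 and 767.5 UMIs). Of 8 heat shock protein genes 7 were lower, with a median of -0.39 (percentile 0.62), the lowest being the mitochondrial chaperonin gene Hspd1 (52 and 22 UMIs, -1.05, -1.84 to -0.304).

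The imprinted gene Peg3 was 2.87-fold lower in MNPQ neuron-like cells (499 and 174 CPM), and the microtubule-associated protein gene Map1b was 2.14-fold lower (1470 and 688 CPM). Further low ratios were those of Gprasp1 (-1.43), Gm42418 (-1.33), Map7d2 (-1.27), Tax1bp1 (-1.27), AY036118 (-1.19), Macf1 (-1.19), Malat1 (-1.17) and Ddx24 (-1.11). Further high ratios were those of Clstn1 (1.48), the protein kinase C gene Prkcb (1.41), the metallothionein gene Mt2 (1.31), Tcf4 (1.26), Gde1 (1.19), Nptxr (1.14) and Lgmn, whose ratio of 1.16 turned to -0.0174 with cells thinned to 1000 UMIs. Thinning kept only the 39 control and 50 MNPQ neuron-like cells with at least 1000 UMIs. In those thinned cells the median of the synaptic genes was 0.231 and the ratios were 0.152 for Slc17a7 and -2.47 for Gprasp1. The ratio of Tcf4 was 0.343 with a class per cell from marker scores, those of Malat1 and Nptxr were -0.757 and 0.615 without a cell filter, and in cells with at least 500 genes and at most 10% mitochondrial UMIs the ratios were -0.819 for Peg3, -0.664 for Map1b, -1.84 for Ddx24 and 2.38 for Clstn1.

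In microglia-like cells, immediate early genes were lower in the MNPQ library, where ribosomal protein genes were slightly higher. The comparison rests on 158 control cells with 339374 UMIs and 118 MNPQ cells with 244685 UMIs. Jun (ENSMUSG00000052684), a subunit of the AP-1 transcription factor, was 3.16-fold lower (969 and 307 CPM, log2 ratio -1.66, -2.04 to -1.3), and Nfkbia, the inhibitor of NF-kB, was 2.42-fold lower (197 and 81.7 CPM). Of 13 immediate early genes 9 were lower, with a median of -0.47 (percentile 0.155 of random lists), and the highest was Zfp36 (0.20, -0.31 to 0.70). Of 64 ribosomal protein genes 53 were higher, with a median of 0.18 (percentile 99.83), which was 0.031 in cells with at least 500 genes and at most 10% mitochondrial UMIs. Of 13 homeostatic microglia genes 10 were lower, with a median of only -0.094 (percentile 2.355), and this median turned to 0.050 under that same filter. The lowest of them was Slc2a5 (-0.54). All 11 measured genes of the disease-associated microglia list were higher, but their median of 0.21 lay inside the range of random lists (percentile 93.31).

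Other low ratios in microglia-like cells were those of Gm42418 (-1.53), the RNA-binding protein gene Ewsr1 (-1.38), Gtf2h2 (-1.36), Tax1bp1 (-1.26), Bcas2 (-1.24) and Pafah1b1 (-1.18). The chromatin remodeller gene Atrx (-1.43) and Nav3 (-1.17) turned to 0.172 and 0.0657 with cells thinned to 1000 UMIs, where Jun was at -1.08, Ewsr1 at -0.471, Gtf2h2 at -0.49, B430010I23Rik at 0.462, Rps27 at 0.301 and both Rnh1 and Cd48 at 1.65. With each cell weighted the same, the ratio was -0.327 for Nfkbia, and the medians were -0.836 for immediate early and 0.085 for ribosomal protein genes. High ratios were those of B430010I23Rik (1.31), the glycolipid transfer protein gene Gltp (1.11), Dhrs3 (1.06), Rps27 (0.952), Acads (0.944), Rnh1 (0.908), Pon2 (0.896) and Cd48 (0.887). Mbp, a myelin gene and marker of oligodendrocytes, was 2.02-fold higher (934 and 1880 CPM), and oligodendrocyte-like cells were 6.12% of the control and 9.48% of the MNPQ library. Of 5 myelin genes measured in microglia-like cells 3 were higher, with a median of 0.55 (percentile 99.655), which turned to -0.148 when genes with as few as 5 UMIs were taken and was 0.033 with the clusters weighted equally, where the ratio of Mbp was 0.231. In cells with at least 500 genes and at most 10% mitochondrial UMIs, the ratio of Mbp was 1.53 and that of Gm42418 was -0.888. An Mbp UMI was seen in 57.0% of control and 72.9% of MNPQ microglia-like cells, and in 59.7% and 76.4% of neuron-like cells, where the gene is not expected either.

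**Figure D3:**
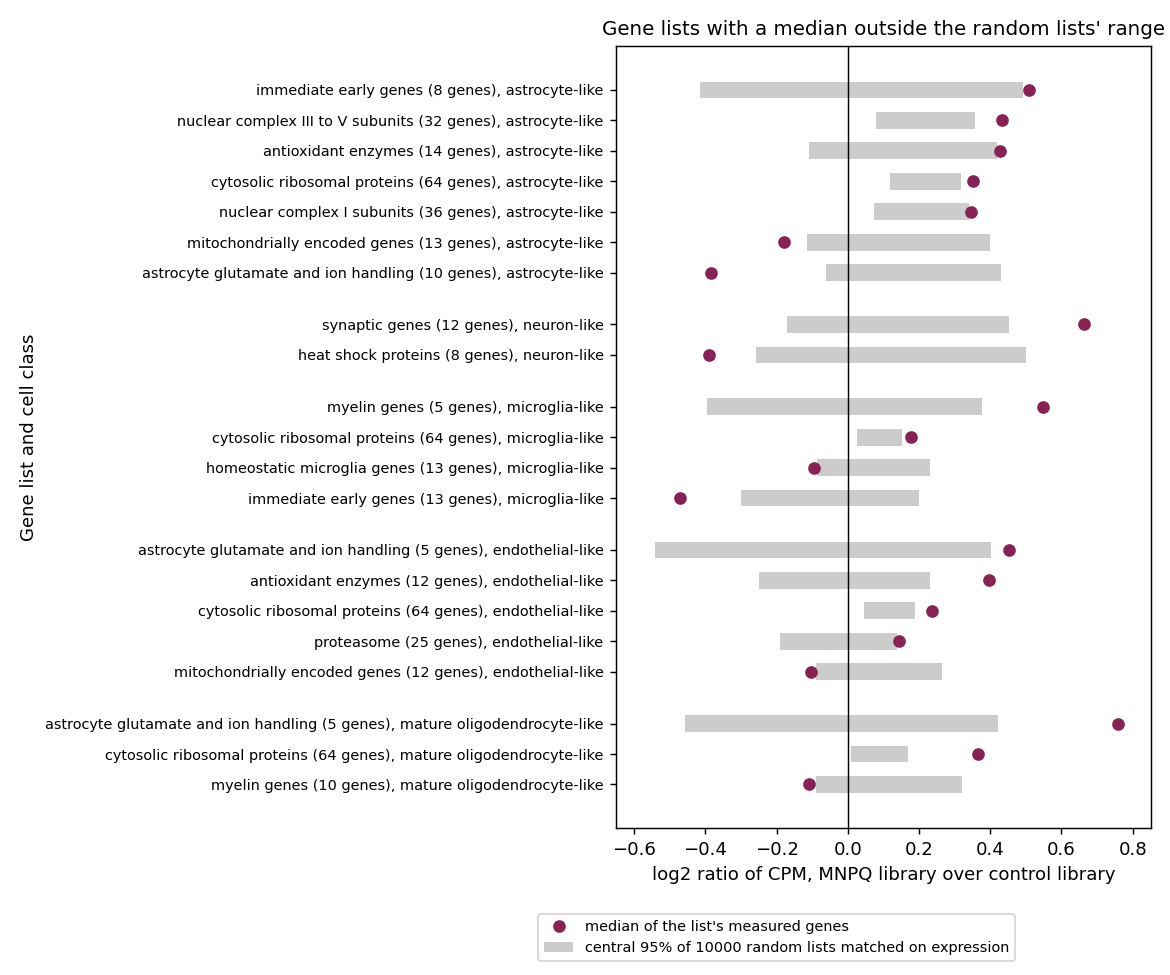
Median log2 ratio (MNPQ over control library) of the lists outside the central 95% of 10000 random lists matched on expression (grey bars), by cell class, with the number of measured genes. The medians run from -0.47 for immediate early genes in microglia-like cells, which stayed negative under each scaling tried, to 0.758 for glutamate and ion handling genes in oligodendrocyte-like cells.

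In endothelial-like cells, antioxidant enzymes were mostly higher in the MNPQ library. Of 12 measured enzymes 11 were higher, with a median of 0.40 (percentile 99.98 of random lists), and the most abundant, the lipid peroxide-reducing Gpx4, was at 288 and 408 UMIs (0.42, 0.20 to 0.64). Red cell transcripts were higher in this class too: hemoglobin genes made up 1.08% of its control and 2.82% of its MNPQ UMIs, with Hbb-bs at 923 UMIs in 13 cells and 4291 UMIs in 6 cells. Without the 2 control and 2 MNPQ cells that had over 1% hemoglobin UMIs, the antioxidant median was 0.363. Ribosomal protein genes (61 of 64 higher, median 0.24, percentile 99.98) and proteasome genes (21 of 25 higher, median 0.14, percentile 97.98) were higher too, while 10 of 12 mitochondrially encoded genes were lower (median -0.10, percentile 1.82). The nuclear envelope protein gene Syne1 was 2.99-fold lower (260 and 87.0 CPM), and Gm42418 (4.06-fold) and Arhgap29 (2.83-fold) were lower as well. Lamtor4, a part of the lysosomal Ragulator complex, was 2.94-fold higher (54.7 and 161 CPM), followed by Wbp2 (2.72-fold) and Hdgf (2.3-fold). The comparison rests on 73 control and 68 MNPQ cells with 292536 and 310488 UMIs. Of 12 blood-brain barrier genes 5 were higher and 7 lower (median -0.06, percentile 5.71), which lay inside the random range. Of 5 measured genes of the astrocyte list for glutamate and ion handling 4 were higher (median 0.45, percentile 98.405). With each cell weighted the same the ribosomal median was 0.407, and with cells thinned to 1000 UMIs it was 0.394 and the ratio of Arhgap29 was -2.32.

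In mature oligodendrocyte-like cells, Glul (ENSMUSG00000026473), the glutamine synthetase gene, was 2.53-fold higher in the MNPQ library (1410 and 3570 CPM, log2 ratio 1.34, 1.17 to 1.51). All 64 ribosomal protein genes were higher (median 0.37, percentile 100 of random lists). Of 10 myelin genes 9 were lower by a small margin (median -0.11, percentile 1.82), with Mal the lowest at -0.487, but that median turned to 0.039 with cells thinned to 1000 UMIs. Sort1, the sorting receptor sortilin, was 2.95-fold higher (63.8 and 188 CPM), and Hdgf was 2.52-fold higher. Of the astrocyte list for glutamate and ion handling, which holds Glul, 5 genes were measured and 5 were higher (median 0.758, percentile 99.995). Gm42418 was 9.19-fold lower (2670 and 291 CPM), the cohesin gene Smc3 2.65-fold lower and Ppig 2.48-fold lower. The comparison rests on 54 control and 81 MNPQ cells with 234997 and 409334 UMIs. With cells thinned to 1000 UMIs the ratio of Sort1 was 3.89, against a log2 ratio of 1.56 without thinning.

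Over all kept cells, the lowest ratios followed the class shares in part. Spag6l (-3.26), Cep126 (-2.57) and Rpgrip1l (-2.18), genes of cilia, had their highest level in ependymal-like cells, the class at 3.17% of the control and 0.703% of the MNPQ library. Itih3 (-2.36) had its highest level in astrocyte-like cells. The highest ratios were those of Ppp1r3g (2.08), the neuronal translation factor gene Eef1a2 (1.97), Igfbp2 (1.81), the pacemaker channel gene Hcn2 (1.79) and Rpusd3 (1.73). All 10 myelin genes were higher (median 0.68, percentile 100 of random lists), but with the classes weighted equally their median turned to -0.104. All 13 homeostatic microglia genes were lower (median -0.52), and 6 of 7 complement genes (median -0.45), at microglia-like shares of 17.9% and 13.8%. With the classes weighted equally those medians were -0.097 and -0.058, and the ratios were -1.38 for Spag6l, -0.566 for Cep126 and 1.02 for Hcn2. This weighting took the 5 compared classes only and left out ependymal-like cells. The values for Spag6l and Cep126 thus do not show their ratios at an even share of ependymal-like cells. Among 16 cholesterol synthesis genes 13 were higher (median 0.36, percentile 99.94), led by Fdps (0.947, 0.671 to 1.23). Within astrocyte-like (0.214), neuron-like (0.012), endothelial-like (0.279) and oligodendrocyte-like (0.241) cells, the median of that list lay inside the random range. Synaptic genes (10 of 12 higher, median 0.56) had the same direction as in neuron-like cells. Complexes III to V (32 of 32 higher, median 0.25) and glutamate and ion handling (7 of 10 lower, median -0.275) had the same direction as in astrocyte-like cells. In neuron-like cells 4 of 5 measured glutamate and ion handling genes were higher (median 0.296), inside the random range. Ribosomal protein genes were mostly higher in each of the 5 compared classes. In neuron-like cells (56 of 62 higher, median 0.257) and over all kept cells (63 of 64, median 0.207) their median lay inside the random range. A response of single classes is thus not told apart from a difference of the whole libraries for these genes.

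Gm42418 was among the lowest genes of each compared class, and over all kept cells it was 6.69-fold lower (3630 and 543 CPM, log2 ratio -2.74, -2.84 to -2.65). Gm42418 (ENSMUSG00000098178) lies on chromosome 17 (39846958 to 39848788, plus strand), and AY036118 (39847113 to 39848035, minus strand) lies within it. The long noncoding RNA Malat1, which stays in the nucleus, lies on chromosome 19 (5795690 to 5802672) and made up 5.75% of control and 3.77% of MNPQ UMIs in kept cells. Across the 10 named classes, Gm42418 was lower in 10 (log2 ratios of -4.45 to -1.33), AY036118 in 10 (-3.48 to -0.832) and Malat1 in 10 (-1.19 to -0.277). The lowest AY036118 ratio was that of ependymal-like cells, with 54 UMIs in the control and 1 in the MNPQ library. The lowest Malat1 ratio was that of vascular fibroblast-like cells, where all 354 control UMIs lay in 1 of 2 cells. For AY036118 the interval lay below 0 in 7 of them, and it held 0 in oligodendrocyte precursor-like, pericyte-like and vascular fibroblast-like cells, the last with 1 and 3 UMIs. In cells of unnamed clusters Malat1 was at 160 and 204 UMIs (0.198, -0.108 to 0.505). Of these, 139 and 81 lay in a single cell, and 12 of 64 and 7 of 71 cells had a UMI. The direction of Malat1 in these clusters is thus not settled. In all, 131 combinations of a list with a class or with all kept cells had a median, of which 19 lay above and 10 below the central 95% of random lists. By chance 6.55 would lie outside if the genes of a list varied independently. This count measures no excess, since genes of a list can vary together, lists share genes and all kept cells include the cells of each class.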

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

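The comparisons between cell classes given here and the tests of the immediate early gene pattern were chosen after the list medians had been seen, but the outcomes that would count for or against each explanation of that pattern were written before they were run. None of the differences between classes was itself tested, since each group has 1 library.

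Immediate early genes differed in direction between classes: their median log2 ratio in astrocyte-like cells (0.51) minus that in microglia-like cells (-0.47) was 0.979. These medians rest on 8 and 13 measured genes; over the 6 genes measured in both classes the difference was 0.987, and each of the 6 had the higher ratio in astrocyte-like cells. In neuron-like cells 5 of 7 of these genes were higher (median 0.522) and in endothelial-like cells 10 of 14 were lower (-0.211), both inside the range of random lists. A few control cells with very high levels are argued against as the source of the low microglia-like median, because it was -0.5, with 8 of 10 measured genes lower, after the 5 cells with the highest share of these genes were left out of each library. A different mix of microglia-like clusters is argued against as well: within the cluster that holds most of the UMIs, 9 of 13 genes were lower and the median was -0.515. Genes of this kind respond to handling within minutes, so a difference in dissociation between the libraries stays open, as does the treatment, and neither was tested because each coincides with the library.

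Glutamate and ion handling genes, lower in astrocyte-like cells of the MNPQ library, were higher in classes that are not their main source. Their median in endothelial-like cells, over 5 measured genes, exceeded that in astrocyte-like cells by 0.836 on the log2 scale, and by 0.946 over the 5 genes measured in both. In oligodendrocyte-like cells it exceeded the astrocyte-like median by 1.14 (1.34 over the 5 genes in both), with Glul, Slc1a2 and Slc1a3 each higher there (UMIs of 332 and 1462, 18 and 54, and 17 and 53). These are UMIs before scaling, out of 234997 control and 409334 MNPQ UMIs of the class. Whether free RNA adds to them was not tested. Myelin genes had a median in microglia-like cells that exceeded that in oligodendrocyte-like cells by 0.655, or 0.687 over the 5 genes measured in both.

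Cd74, the invariant chain of MHC class II, had 154 UMIs in MNPQ cells of the unnamed clusters, which enter no comparison by class, against 0 UMIs in control cells of those clusters. Of these UMIs, 97 lay in a single cell.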

How the results depend on the processing

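Weighting the clusters of a class equally, leaving out cells with over 1% hemoglobin UMIs and taking only cells with at least 1000 UMIs were chosen only after the data were seen. Under an alternative, 82 of 88 share differences stayed within 0.5 counting interval widths of the main value. Of 203 list medians 177 stayed within 0.5 widths of the range of random lists, 21 moved and 5 changed sign. Of 708 named gene ratios 648 stayed within the counting interval, 57 moved and 3 changed sign. The causes of the moves below were not tested. With at least 500 genes and at most 10% mitochondrial UMIs, the share differences were -4.89 percentage points for ependymal-like and 7.36 for oligodendrocyte-like cells, and the medians were 0.469 for ribosomal genes in astrocyte-like and 0.031 in microglia-like cells, and 0.050 for homeostatic genes in microglia-like cells. With at least 1000 UMIs, the share differences were -4.44 (ependymal-like) and 6.29 (oligodendrocyte-like). That of neuron-like cells was -0.814 without a filter, and that of vascular fibroblast-like cells -0.307 with a class per cell from marker scores. With cells thinned to 1000 UMIs and shallower cells left out, complex I (0.715), complexes III to V (0.935) and ribosomal genes (0.46) in astrocyte-like cells moved, as did ribosomal genes in endothelial-like (0.394) and oligodendrocyte-like (0.509) cells, synaptic genes in neuron-like cells (0.231) and myelin genes in oligodendrocyte-like cells (0.039). Thinning also turned Lgmn in neuron-like cells (-0.0174) and Atrx (0.172) and Nav3 (0.0657) in microglia-like cells. Scaling the class median to 0 gave 0.18, 0.269 and 0.188 for complex I, complexes III to V and ribosomal genes in astrocyte-like cells. Equal cell weights gave 0.048 for mitochondrially encoded genes in astrocyte-like cells, 0.085 and -0.836 for ribosomal and immediate early genes in microglia-like cells, and 0.407 and 0.466 for ribosomal genes in endothelial-like and oligodendrocyte-like cells. Equal cluster weights gave 0.142 for antioxidant enzymes and 0.275 for complexes III to V in astrocyte-like cells, and 0.033 for myelin genes in microglia-like cells. With list genes of at least 5 UMIs, microglia-like medians were -0.769 for immediate early and -0.148 for myelin genes. With the 5 compared classes weighted equally and the other classes left out, the myelin median was -0.104. Some thinned or equally weighted lists had too few genes or clusters for a value. No paired analysis and no leaving out of a replicate was possible, because each group has 1 library. Depth is a limit for single cells, as 50.1% of control and 52.1% of MNPQ cells had under 1000 UMIs.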

Other observations

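The tests of this part, the regional lists and the single genes described here were chosen after the class comparisons had been seen, and the tests on transcription factors alone, without Hap1 and on Malat1 in removed barcodes were chosen after the values they rest on had been seen.

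Neuron-like cells of the libraries carried transcripts typical of different brain regions. Pmch, the precursor of the hypothalamic melanin-concentrating hormone, had 102 UMIs in neuron-like control cells, 82 of them in 1 cell, and 0 UMIs in 144 neuron-like MNPQ cells. A Pmch UMI was seen in 9 of 124 neuron-like but also in 10 of 321 astrocyte-like and 4 of 158 microglia-like control cells, so most of these cells are not told apart from a background of free RNA. Avp and Oxt, the vasopressin and oxytocin genes of the hypothalamus, had 24 and 20 UMIs in neuron-like control cells, of which 23 and 20 lay in a single cell, and 0 UMIs in neuron-like MNPQ cells. Slc17a6, the vesicular glutamate transporter of most subcortical neurons, was at 25 and 7 UMIs (log2 ratio -1.64, -3.1 to -0.394). Neurod6, a transcription factor of cortical and hippocampal neurons, was at 2 and 18 UMIs (3.36, 1.3 to 6.51), and the neuropeptide gene Cck at 62 and 162 UMIs (1.58, 1.15 to 2.02). In astrocyte-like cells, Agt, which is high in astrocytes outside the telencephalon, was at 1053 and 364 UMIs (-1.49, -1.67 to -1.32), and the telencephalic factor Lhx2 at 40 and 81 UMIs (1.06, 0.496 to 1.64). Genes typical of ventral midbrain neurons, as a list of 11, had 9 and 17 UMIs in neuron-like cells. In astrocyte-like cells nearly all UMIs of that list came from Aldh1a1 (49 of 50 in the control and 48 of 49 in the MNPQ library). Without Aldh1a1, 5.65% of control and 6.94% of MNPQ neuron-like cells had a UMI of the list (7 and 12 UMIs, most of them of Nr4a2, at 4 and 11), against 0.312% and 0.329% of astrocyte-like cells (median depth 787.5 and 788 UMIs in neuron-like, 823 and 767.5 in astrocyte-like cells). Foxa1, Foxa2, Pitx3, En1 and En2 of the list had 0 UMIs in neuron-like cells of both libraries. Lmx1a, Lmx1b and Chrna6 had 1 UMI each in the control and 0 in the MNPQ library.

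A pair of MNPQ barcodes in the unnamed clusters had the transcripts of B cells. Igkc, an immunoglobulin light chain gene, had 73 UMIs in 2 MNPQ cells and 0 in the control, and the B cell receptor gene Cd79a had 16 UMIs in 2 MNPQ cells and 0 in the control. Other B cell genes were not absent from control cells of those clusters. Ighm had 44 UMIs in 5 MNPQ and 9 UMIs in 6 control cells, and Cd79b had 18 and 1 UMIs. The MHC class II genes Cd74 and H2-Aa had 154 and 45 UMIs in those clusters of the MNPQ library and 0 in the control. These barcodes held 97 and 53 of the 168 Cd74 UMIs of the MNPQ library, and over all kept cells the MHC class II list had a median log2 ratio of 2.76 (4 of 6 genes higher). Apoe, a lipid carrier gene, was at 1100 CPM in control and 5970 CPM in MNPQ microglia-like cells, but 1204 of its 1461 MNPQ UMIs lay in a single cell.

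The regional transcripts may reflect a different regional make-up of the dissected tissue. A difference in depth is argued against, since in neuron-like cells thinned to 500 UMIs the log2 ratio of a 15-gene cortical and hippocampal list exceeded that of a 16-gene hypothalamic list by 1.6 (1.04 to 2.16). More hypothalamic neurons in the control library cannot be told apart from a different level of single genes: with the richest cell of each library left out the list was at -0.478 (-0.859 to -0.102), the outcome written beforehand for this explanation, but at -0.268 (-0.695 to 0.156) without Hap1, and its 5 transcription factors, on 5 and 1 UMIs, were at -2.13 (-7.69 to 1.03). Nor can more cortical or hippocampal neurons in the MNPQ library be told apart from that: the whole list was at 0.62 (0.427 to 0.814), again the outcome written beforehand, but its 9 transcription factors were at 0.171 (-0.193 to 0.535), with Bhlhe22 at 9 and 0 UMIs. The treatment stays open, untested, because it coincides with the dissection.

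Gm42418 and Malat1 were lower in the MNPQ library in each of the 10 named classes, with intervals below 0, and AY036118 was lower with an interval below 0 in 7 of them. In unnamed clusters Malat1 was at 0.198 (-0.108 to 0.505), but 139 of its 160 control and 81 of its 204 MNPQ UMIs lay in a single cell. A difference of the whole library, in barcodes of any kind, is a candidate explanation for Gm42418, which was lower also in the barcodes that the cell filter removed (-2.22, -2.61 to -1.85). For Malat1 the removed barcodes cannot decide. Its summed level was higher there (0.747, 0.651 to 0.844), but a UMI of it was seen in 60.5% of 223 control and 45.9% of 111 MNPQ barcodes. Hemoglobin took 23.13% and 17.91% of the UMIs of these barcodes, so their make-up differed as well. Without Gm42418, AY036118 and Malat1 in the totals, the astrocyte-like ribosomal protein median was 0.287, against 0.352 with them. The size of this shift is set by the share of UMIs these RNAs take. It shows only that their part in the totals accounts for some of that median and not all of it. Less nuclear RNA in the MNPQ library cannot be told apart from counting error: 4 other nuclear long noncoding RNAs were at -0.253 (-0.615 to 0.107), on 145 and 119 UMIs. The treatment as the cause was not tested, since it coincides with the library.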
